A study of Mus musculus with 18 samples.

How the data were processed

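Genomic DNA from the tails of 9 C57BL/6 mice was measured by array comparative genomic hybridization. In this assay, 2 DNAs labelled with different dyes compete for the same probes. The animals were 1 sire, 1 dam and 7 of their progeny, per the labels all of a non-irradiated family in a series on exposure of males to 1 mGy of gamma rays a day for 400 days. Each animal was hybridised against 1 reference male, mouse 12 of the same colony, on 2 arrays with the dyes exchanged, which gave 18 arrays. The 2 arrays of an animal were a technical dye swap and counted as 1 replicate.

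Per the file headers, the scans were read with Agilent Feature Extraction 10.7.1.1, and probe positions referred to the mouse build mm9. The deposited intensity values used were the processed signals of both channels, background-subtracted and dye-normalized by linear factors within each array, per the file headers. The deposited median signals and local background intensity values served 1 alternative. The deposited LogRatio column was on a log10 scale, red over green, per the file headers, and was used only to check the direction of the processed signals. The authors' value table was on a log2 scale as found by comparison with the scanner values, and served as an alternative. The method behind that table is not given in the sources used here.

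The value table and the scanner files disagreed on which array is which. Each of the 18 columns correlated at 0.987 to 0.997 in size with 1 scanner file, with the sign turned, and this was in every case the array at the mirrored place in the series. Correlations of a column with the array of its own name lay between 0.112 and 0.322 across spots. Column medians lay between -0.0069 and 0.0179. These correlations do not show which of the 2 is named wrongly. The scanner files were taken as right, because their X medians then went with the labels of the sire, the dam and the male reference, and every animal's values depend on this choice. The alternative based on the table used the matched columns. Scale and centring of the table were found in this way, while any other step behind it stays unknown.

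From each array, 966371 spots other than controls were read, with 108 to 400 spots flagged as non-uniform or population outliers removed. The log2 ratio of the animal over the reference was taken from the processed signals, with the direction set by the dyes in the labels. Spots of the same probe were averaged, which left 949631 autosomal probes, 68 probes on X and 23 probes on Y. The median spacing of neighbouring autosomal probes was 2054 bp. Each array was centred on its autosomal median, with no loess and no quantile step, and the 2 orientations of an animal were averaged.

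Regions were called per animal and chromosome with an interval scan. The score was the size of the summed log2 ratios divided by the robust SD of the animal's autosomal log2 ratios times the root of the number of probes. A call needed a score of at least 6, at least 3 probes and a mean of at least 0.25 in size. Each orientation alone had to give the same sign and a mean of at least 0.25 in size. Calls of the same direction sharing at least 1 probe were merged across animals, and means of a region were taken over the probes called in at least 50 percent of its carriers. A region counted as called in progeny and in neither parent only if the mean of at least 1 progeny carrier differed from that of each parent by at least 0.25. For regions called in exactly 1 parent and in progeny, carriers among the 7 progeny were set against an even chance by an exact two-sided binomial test with Benjamini-Hochberg adjustment.

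The background of the calling was measured with the same scan on the dye component, in which copy number cancels, divided by its own robust SD, and on probes shuffled within each chromosome. The shuffle was run with an order drawn per animal, and also with the same order in all 9 animals, which keeps what the animals share through their common reference. Scanning the dye component at the robust SD of the animal's log2 ratios was an alternative, and its own SD was kept as the main scale after both counts had been seen. A stricter rule with a score of at least 8 and at least 5 probes was added after seeing the data.

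The scanner files named no genes, and no gene annotation of mm9 was used here. The planned test per gene was therefore replaced, after seeing the files, by 50 kb windows with at least 3 probes. Window means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 coefficient each for sire, dam and progeny. The progeny coefficient was tested against 0, with Benjamini-Hochberg adjusted p under 0.05 and a size of at least 0.25. All adjusted p-values of windows come from limma. The 20 gene lists fixed for this study were not tested for the same reason. Sire and dam were single animals, so their values carried no test.

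Named regions followed a rule. It took up to 10 regions called only in progeny by size in the strongest carrier, and up to 10 called in a parent and in progeny by number of carriers and then size. It also took up to 5 called in all 9 animals, up to 5 called in a parent only by size, and the 10 largest rises and falls of the window fit with the same sign in 7 progeny. The genes that the rule also asked for were not named. Regions outside the rule are said to have been chosen after their values were seen. Calls, family classes, the binomial test and most alternatives were fixed before the data were examined. The window fit and the tests of explanations named below as chosen later were not.

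The scan was tested on simulated data by adding known changes to shuffled probes of each animal. Over 949631 probes it found 100% of 117 losses of 1.0 on the log2 scale over 3 probes in the 9 animals, 79.5% of 117 gains and 70.9% of 117 losses of 0.55 over 3 probes, and 100% of 108 gains of 0.55 over 10 probes. Over 3 probes a change of 0.55 was found in 13 of 13 gains and 13 of 13 losses in progeny 2, but in 5 of 13 gains and 2 of 13 losses in progeny 3. Gains of 0.3 were found in 16.2% of cases over 3 probes and in 94.4% over 30 probes. The window fit called all 50 windows changed at each of 4 sizes from -0.6 to 0.6 among 46711 simulated windows, and 0 unchanged windows. These windows were drawn as independent normal values around 0 with the SD of each window over the progeny. They held no effect of the shared reference, so this does not measure false calls in the real data.

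Alternatives were normexp background correction with an offset of 50, loess within each array with a span of 0.3, the value table, stricter scores, sizes and probe numbers, single dye orientations, and no rule on each orientation. Others were outlier-flagged spots kept, dim or saturated probes left out, a running median over 2 Mb taken off, other merging and other window settings. Calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. The 36 spots on unplaced sequence were left out.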

Results

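The series asked whether DNA copy number changes arise in the offspring of mice, and this part held 1 family without irradiation. It comprised a sire, a dam and 7 progeny, each compared with the same reference male on 2 arrays of exchanged dyes. Between 94.9% and 99.98% of spots lay well above background in both channels of an array. The spread of log2 ratios between neighbouring probes ranged from 0.156 to 0.350 over the 18 arrays. The robust SD of an animal's averaged log2 ratios was lowest in progeny 2, at 0.08, and highest in progeny 3, at 0.18. Across autosomal probes, arrays of the same dye orientation correlated at 0.143 to 0.440 and arrays of opposite orientation at -0.441 to -0.092, with all ratios turned to the animal over the reference. The latter include the 2 arrays of each animal, which correlated below 0 in all 9 animals, from -0.092 in the dam to -0.441 in progeny 2. The number of arrays limits the precision. Arrays were scanned on 5 days, with the parents alone on scan day 1, progeny 1 and 2 on day 2, progeny 3 and 4 on day 3, progeny 5 and 6 on day 4 and progeny 7 on day 5. No day held both a parent and progeny, so scan day and generation cannot be told apart.

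The dam carried more X and less Y signal than the reference male, and the sire did not. The median over 68 X probes was 0.92 in the dam and 0.01 in the sire. Over 23 Y probes the medians were -2.20 and 0.06. Progeny 1 and 2 had X medians of 0.00 and 0.01 and Y medians of 0.01 and 0.06. X medians in progeny 3 to 7 were 0.95, 0.94, 0.96, 0.95 and 0.95, and their Y medians were -2.23, -1.94, -2.41, -2.24 and -2.16. By both X and Y signal, progeny 1 and 2 were thus like the sire and the reference male, and progeny 3 to 7 like the dam. The sex of the progeny was not in the labels, and no test between animals was made. With the dye orientations taken singly the X median of the dam was 0.92 in each. Normexp background correction lowered the X medians of the dam and of progeny 3 to 7, as given with the other processing settings below.

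**Figure D1:**
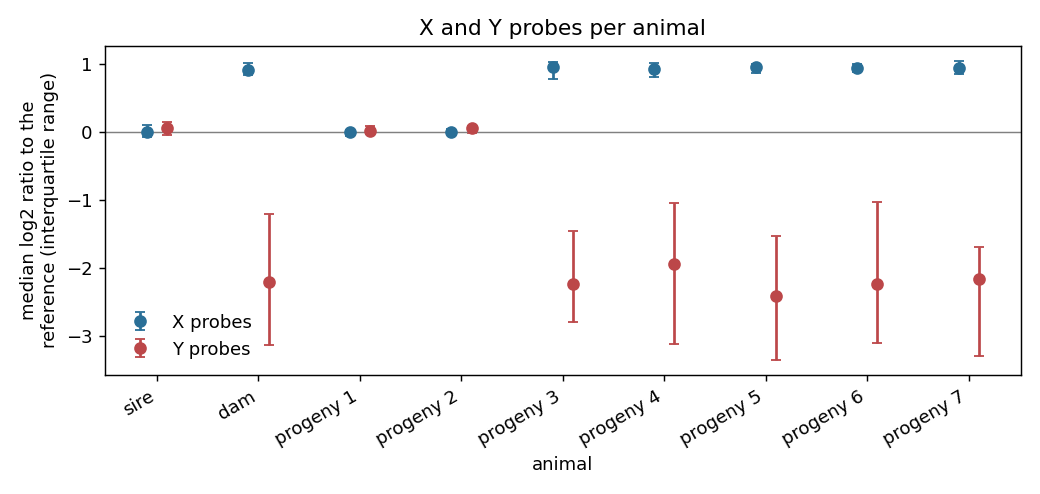
Median log2 ratio to the reference male over X probes (blue) and Y probes (red) for the sire, the dam and each of 7 progeny, with bars for the interquartile range over probes. The dam and progeny 3 to 7 sit near 0.92 to 0.96 for X, and the other animals near 0.

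One long gain was called in the sire and in 2 of 7 progeny. It lay on chromosome 4 from 101110482 to 101270535 (mm9, 74 probes) and was chosen after its values were seen. Its mean log2 ratio was 0.56 in the sire, 0.54 in progeny 6 and 0.55 in progeny 7. The scan placed its first and last probe at the same positions in these 3 animals. In the other 6 animals its mean was at most 0.04 in size, against a log2 value of 0.58 for 3 copies over 2. The best score was 45.3, and the 2 carriers of 7 gave p = 0.453 by the exact two-sided binomial test (adjusted p = 0.526). With at least 1 progeny carrier needed for a region to enter, only 7 carriers could give p under 0.05 by this test before adjustment. After adjustment over the 58 regions tested, even that need not pass.

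Both regions called in all 9 animals were losses against the reference. On chromosome 10, from 33897213 to 33934959 (20 probes), the mean was -0.58 ± 0.03 (SD, n = 9 animals), from -0.65 to -0.55. The log2 value of 2 copies over 3 is -0.58. In 7 of the 9 animals the call ended at 33933441 after 19 probes and began at the same probe. On chromosome 14, the merged calls ran from 53387255 to 54386805 (109 probes), with a mean of -0.27 ± 0.03 (SD, n = 9 animals) over 80 probes. Calls of single animals differed in length, so the whole span was not called in all 9. The longest call of the dam ended at 53954595 and that of progeny 3 at 53961747, against 54386805 in the sire. Depth varied along this interval. Bins of 50 kb averaged -0.15 from 53400001, -0.32 from 53500001, -0.51 from 53700001, 0.01 from 54050001 and -0.12 from 54350001. Both losses were called under each of the 17 alternatives in which regions were counted.

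**Figure D2:**
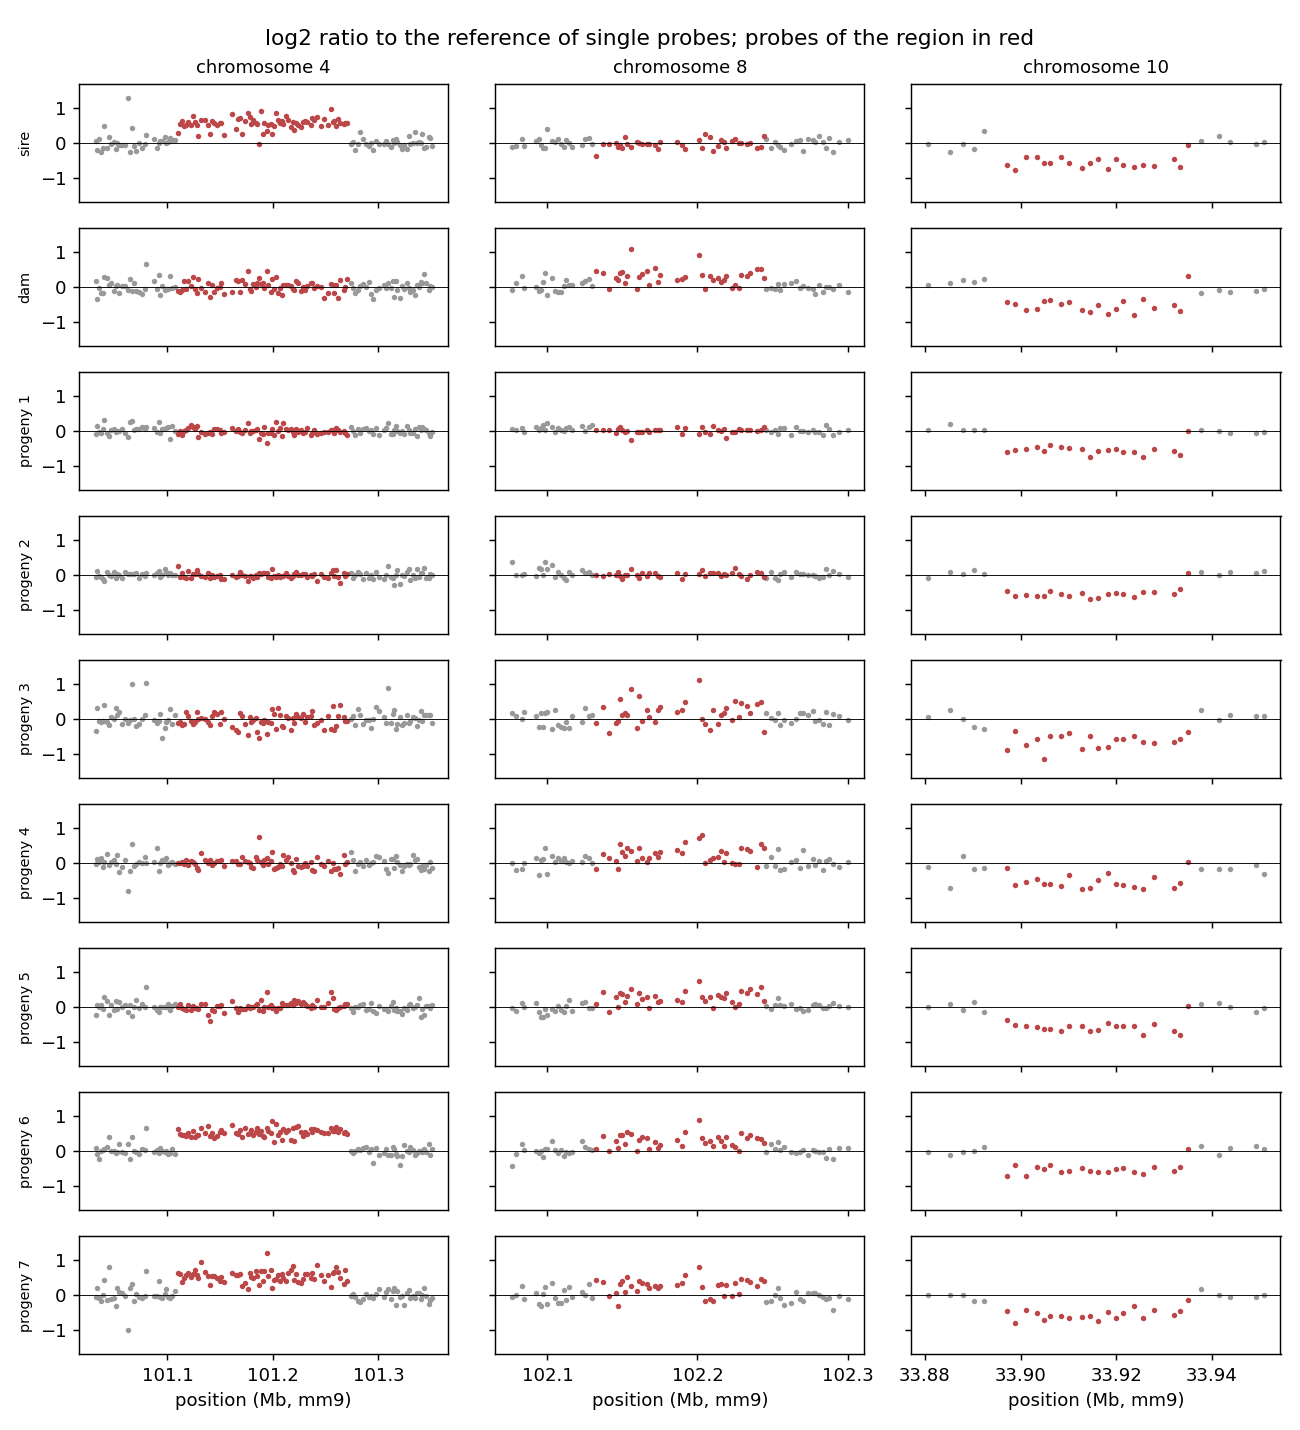
log2 ratio to the reference of single probes (points) by position in Mb on mm9 around the regions on chromosomes 4, 8 and 10, with one row per animal and the probes of each region in red. The chromosome 4 probes are raised in the sire, progeny 6 and progeny 7, and the chromosome 10 probes average below 0 in all 9 animals.

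**Figure D3:**
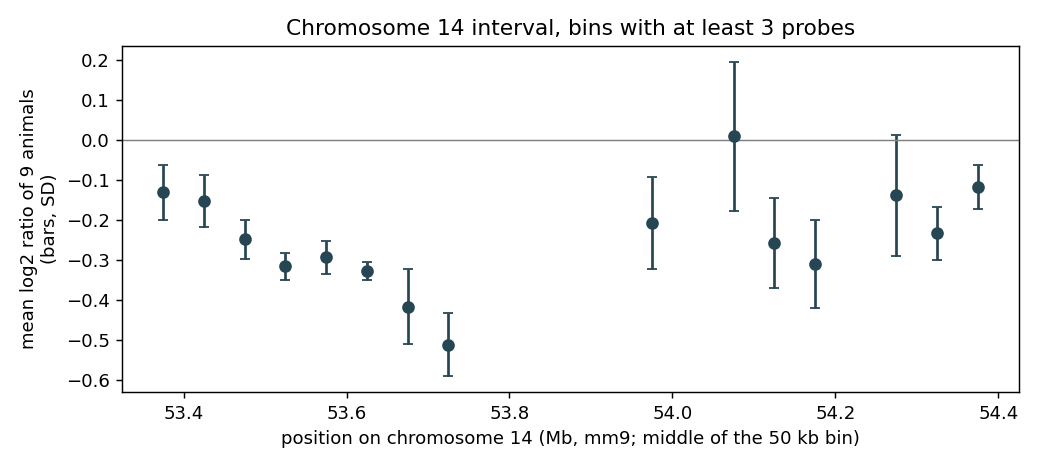
Mean log2 ratio of the 9 animals (points, with bars for the SD) in 50 kb bins with at least 3 probes along the chromosome 14 interval, by position in Mb on mm9. The lowest bin averages -0.51.

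The dam shared a set of regions with some of the progeny. The longest was a gain on chromosome 8 from 102132083 to 102244157 (39 probes). Its mean was 0.29 in the dam, 0.25 in progeny 4, 0.28 in progeny 5, 0.31 in progeny 6 and 0.25 in progeny 7, all called. It was 0.20 in progeny 3, not called, and -0.03, 0.00 and 0.01 in the sire, progeny 1 and progeny 2. The deepest was a loss on chromosome 3 from 25417435 to 25432738 (3 probes), called in the dam at -1.51 and in progeny 3 to 7 at -1.34, -1.44, -1.61, -1.60 and -1.52. Its means in the sire, progeny 1 and progeny 2 were 0.01, 0.07 and -0.03.

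Losses with carriers among the same 6 animals lay on chromosome 6 from 104236953 to 104250021, on chromosome 5 from 123592752 to 123603094 and on chromosome 3 from 132546474 to 132553080. Their means in the dam were -0.80, -0.64 and -0.79. Further ones lay on chromosome 9 from 35851444 to 35865189, on chromosome 16 from 40847733 to 40856111 and on chromosome 16 from 38039261 to 38047978, at -0.46, -0.31 and -0.47 in the dam. In at least 1 carrier of each of these 6 losses a single probe made up between 82.7% and 96.1% of the summed size.

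In all, 62 regions were called in a parent and in progeny, the pair of losses in all 9 animals included. The rule also named a gain on chromosome 1 from 131173215 to 131193520, called in the dam at 0.50 and in progeny 1, 6 and 7, which normexp took to -0.014 in the dam. It further named a gain on chromosome 10 from 43897432 to 43913117, called in both parents and in progeny 6 and 7, at 0.45 in its strongest carrier. Of the 58 regions called in exactly 1 parent and in progeny, 37 were called in the dam and 21 in the sire, and 38 had a single progeny carrier. The carriers were tested against an even chance (smallest p = 0.125 by the exact binomial test, adjusted p = 0.191). Regions entered only with a progeny carrier, and 1 to 6 carriers of 7 cannot give a smaller p, so this test decides nothing. With the same probe order shuffled in all 9 animals, 53 regions were called in a parent and in progeny, and none in all 9. With an order per animal there were 7. Under the stricter rule, added after seeing the data, the counts were 9 observed, 2 shuffled in the same order and 0 with an order per animal.

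Calls in progeny but in neither parent numbered 860 regions, 449 gains and 411 losses. A further 242 regions (202 gains and 40 losses) were called in progeny and in neither parent but failed the rule on the difference. Together these made 1102, against 1124 with probes shuffled in the same order and 1269 with an order per animal. Of the 860 regions that met this rule, progeny 3 carried 303, progeny 4 carried 224, progeny 7 carried 168, and progeny 2 carried 12. The largest was a gain of 1.12 in progeny 4 on chromosome 2 from 61020857 to 61026325, where 1 probe made up 94.1% of the summed size and the orientations gave 1.71 (Cy5) and 0.53 (Cy3). Progeny 3 was the strongest carrier of the next 9. Losses among these lay on chromosome 1 from 189463761 to 189468736 (-0.999), chromosome 10 from 102625723 to 102631551 (-0.99), chromosome 16 from 8862228 to 8866315 (-0.94) and chromosome 3 from 108116402 to 108122438 (-0.92). Gains lay on chromosome 9 from 106208532 to 106213755 (0.96) and from 28663855 to 28668568 (0.95). Others lay on chromosome 4 from 134772442 to 134777032 and from 139217596 to 139228330 (0.92 each), and on chromosome 14 from 76952881 to 76957359 (0.91). At the region from 139217596 the dam lay at 0.38, under 0.25 below carrier progeny 6 at 0.53, and the stricter rule classed it as close to a parent.

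Each of these 10 means rested on 3 probes. In at least 1 carrier, a single probe made up 83.6% of the summed size of the chromosome 16 loss and between 49.5% and 66.6% of that of the other 8. In all, 685 of the 860 regions held 3 probes. Shuffled probes gave 869 such regions with the same order in all animals and 1176 with an order per animal. The number of regions called only in progeny was therefore not above the shuffled background. Under the stricter rule 24 were observed, against 19 and 47 in the 2 shuffles. Leaving out every spot not well above background on some array removed 75212 probes with no other spot left, X and Y included. Without them 70 regions were observed and 66 were called after shuffling.

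Over all family classes, 1542 autosomal regions were called, 978 gains and 564 losses. After loess within each array the split was 773 gains and 674 losses. Shuffling in the same order for all animals gave 1578 regions, and the dye component gave 542 at its own robust SD. At the animal's SD it gave 5210, and the scale was settled after both counts were seen. Calls per animal ranged from 28 in progeny 2 to 323 in progeny 3, with 242 in the sire and 203 in the dam. They rose with the robust SD of the animal's log2 ratios (Pearson r = 0.891, exact permutation p = 0.00114; Spearman rho = 0.817, exact permutation p = 0.0108, n = 9 animals), the only relation of this kind computed. Without progeny 2 and 3, the farthest from the median SD, r was 0.736 and rho 0.607. A call needed the same size of mean in all animals, overall and in each orientation, so animals of low SD can lose more calls. Without the rule on each orientation, gains of under 5 probes went from 9 to 71 in progeny 2 and from 127 to 143 in progeny 3. In the sire, at an SD between these, they went from 135 to 254. Part of the relation may therefore be built in by this rule, and r and rho were not computed without the rule. Of the 4 scan days with 2 animals, the animal with the higher SD had more calls on 2 days (92 against 28 and 323 against 257, at SDs of 0.092 against 0.076 and 0.183 against 0.152). It had fewer on the other 2 (203 against 242 and 138 against 227, at SDs closer together, 0.140 against 0.130 and 0.104 against 0.103). These 4 pairs are too few to show whether the relation holds within days. Of the autosomal probes 7.97% (75639) had a spot that was dim on some array, against 37.4% of the probes in calls.

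**Figure D4:**
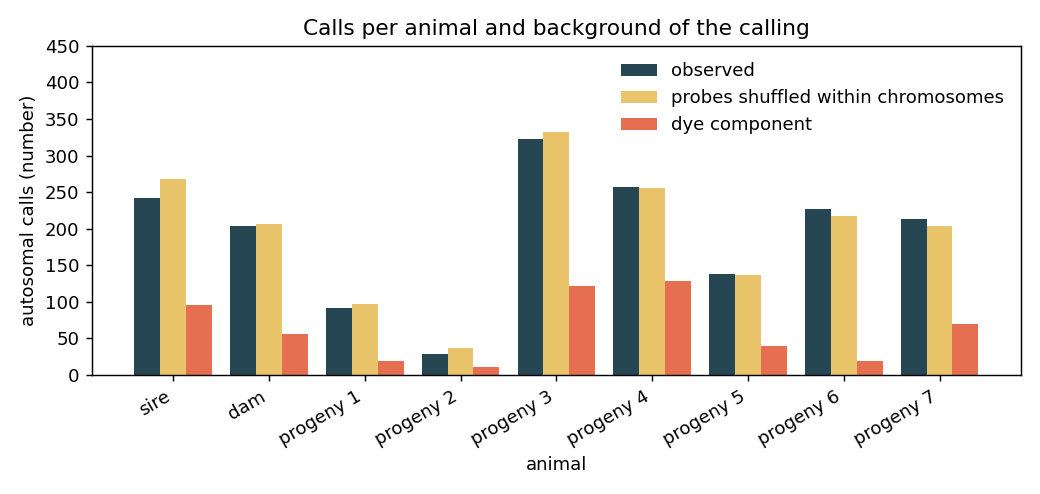
Number of autosomal calls in each animal (bars) as observed, with probes shuffled within chromosomes and in the dye component at its own robust SD. Observed and shuffled counts are 323 and 332 in progeny 3, and 28 and 37 in progeny 2.

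Regions called in 1 parent and in no progeny numbered 378, against 401 with probes shuffled in the same order and 467 with an order per animal, and 305 of the 378 held 3 probes. The largest were losses in the sire on chromosome 2 from 42575684 to 42579547 (-0.82) and from 160814025 to 160819326 (-0.80), and on chromosome 7 from 89121892 to 89125418 (-0.76). Gains in the dam lay on chromosome 7 from 131238762 to 131242874 (0.82) and on chromosome 3 from 91157632 to 91167831 (0.74). Each held 3 probes, and a single probe made up between 68.4% and 89.0% of its summed size. The gain at 131238762 gave 0.33 with Cy5 and 1.30 with Cy3. Progeny 3, where a 3-probe call needed 0.64, lay at -0.51 at the first loss and 0.55 at this gain. At the chromosome 7 loss and the chromosome 3 gain it lay on the opposite side. A missing call in progeny therefore does not show that a change was absent there. Between sire and dam, 37 windows of 50 kb differed by at least 0.25, and 17 of these overlapped a call in exactly 1 parent. The 4 on chromosome 4 covered the gain called in the sire and in progeny 6 and 7. The largest of them, from 101200001, was 0.60 in the sire and -0.01 in the dam. With 1 animal of each kind no test was made.

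Against the reference, 10 of 46711 windows fell in the progeny and 0 rose (limma with Benjamini-Hochberg adjustment; also 10 at an unadjusted p under 0.05 with the size rule). Of these 10 windows, 8 lay in the chromosome 14 interval, 1 in the chromosome 10 loss and 1 over the chromosome 3 loss. The lowest, on chromosome 14 from 53700001, averaged -0.52 ± 0.07 (SD, n = 7 progeny; limma adjusted p = 2.51e-10). The chromosome 10 window from 33900001 averaged -0.45 ± 0.03 (SD, n = 7 progeny; limma adjusted p = 9.17e-12). These p-values rest on the spread among the 7 progeny, as the reference was 1 mouse whose own spread was left out. A copy number difference in that mouse alone could give them. In the chromosome 14 window the sire lay at -0.55 and the dam at -0.38. In the chromosome 10 window they lay at -0.44 and -0.46. Values were below 0 in all 7 progeny in 9 of the 10 windows. The exception, on chromosome 3 from 25400001, averaged -0.31 ± 0.22 (limma adjusted p = 0.0475), with 0.01 in the sire and -0.42 in the dam. There progeny 1 and 2 lay at 0.03 and -0.02, and progeny 3 to 7 between -0.41 and -0.48. The mean and the test took them as 1 group, so they do not describe a fall in all progeny.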

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

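Among the tests below, those of dye bias, of brightness in each animal singly, of the chromosome 10 copy states, of X and Y sequence, of independent inheritance and of the chromosome 8 duplication were chosen after the results were seen. The thresholds of these later tests were set with the values in view. Of 38 sets of values in the 7 progeny, 10 had a sample far from the others, where chance alone gives about 1 in 20. The rule had picked 9 of these regions for their size in 1 carrier, which favours such a gap. Progeny 4 stood apart at chromosome 2 from 61020857, at 1.12. Progeny 3 stood apart at chromosome 1 from 189463761 (-0.999), chromosome 10 from 102625723 (-0.99), chromosome 9 from 106208532 (0.96) and from 28663855 (0.95), and chromosome 16 from 8862228 (-0.94). It also did so at chromosome 3 from 108116402 (-0.92), chromosome 4 from 134772442 (0.92), chromosome 14 from 76952881 (0.91) and chromosome 7 from 89121892 (0.39).

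The authors' value table, which no main value used, gave an X median of -0.96 under the columns named for the sire. The scanner files of the sire gave 0.01. The columns ran in mirrored order against the scanner files, as the correlations across spots showed, and these alone do not tell which of them is named wrongly. The X median of the dam was -0.95 under the table's names and 0.92 in the scanner files. A sire and a dam alike in X argue against the table's names, if the labels of the parents hold.

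Short gains of under 5 probes outnumbered short losses in the dam (162 against 16) and in progeny 6 (189 against 26), and no biological explanation was tested. They also did in progeny 1 (70 against 19), progeny 7 (133 against 64), the sire (135 against 87) and progeny 4 (121 against 115), but not in progeny 2, 3 and 5. In single orientations, losses led with Cy5 and gains with Cy3 in the sire (25 gains against 111 losses, and 309 against 74) and progeny 1, 2, 3, 5 and 7. Gains led in both in the dam and progeny 4 and 6. The tests that follow cover the dam and progeny 6 only. Dye bias stays open: the dye component gave 3.13% as many short gains at its own robust SD and 29.3% at the SD of the animal, where its short losses came to 99.1%, and its sign is arbitrary. Of the short calls in single orientations, 82.1% were gains with the animal in Cy3 and 54.7% with it in Cy5, the latter within 2 standard errors of even, and the 68.7% of gains that reached 0.25 in both with no rule decide nothing, as they were picked by their mean. Shuffled probes gave 102% as many, so single-probe noise with a skewed spread may make them without any change in copy number. After loess on brightness 47.0% of the gains remained, 37.7% in the dam (61, against 76 short losses), where this trend may make the skew, and 55.0% in progeny 6 (104, against 48), which argues against it as the whole cause there.

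The chromosome 10 loss in all 9 animals may be an extra copy in the reference male. Its mean lay 0.34 above the value of 1 copy over 2 at the response the dam's X probes showed (-0.92), which argues against that state with such a response. It lay -0.039 from the value of 2 copies over 3 (-0.54). Probes that also bind elsewhere would weaken the response, and such binding was not analysed here. A state shared by the whole family and absent from the reference stays open, as untested.

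Regions called in the dam and in at least 3 progeny but not in the sire numbered 10, and 90.0% of them had no call in progeny 1 and 2, the progeny with X medians near 0. Sequence shared between these autosomal places and the X or Y chromosome could give this pattern, with 8 losses and 1 gain, but no genome of this build was used to search for copies. The dam's mean at the chromosome 8 gain differed by -0.27 from the sire's at the chromosome 4 gain. If the latter is 3 copies over 2, which was not tested, this argues against such an autosomal duplication at every chromosome 8 probe. Independent inheritance from the dam at each place is argued against, since 8 of the 10 regions, on 6 chromosomes, had the same 5 progeny nearer the dam than the sire. The other progeny, 1 and 2, were also the animals of scan day 2 and the least noisy, so the split among progeny goes with scan day too, while sire and dam lay apart though scanned on the same day.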

How the results depend on the processing

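The stricter rule, the rule on medians, the runs without scan day 3, the value table as named, the second dye scale and the 50 kb, 25 kb and 100 kb windows were chosen after seeing the data. The 2 losses called in all 9 animals and the chromosome 4 gain in the sire were called under all 17 alternatives. The number of autosomal regions (1542) moved to 201 with a score of at least 8, 486 with at least 5 probes, 745 with a mean of at least 0.4 and 2429 with no rule on each orientation. It was 113 with normexp, 228 without dim probes, 58 under the stricter rule, 924 with medians of at least 0.25 and 1021 without scan day 3. Regions only in progeny (860) went, in the same order but for the orientation rule, to 118, 253, 401, 28, 70, 24, 558 and 349, and to 1256 with no rule on each orientation. Those in a parent and in progeny (62) went to 11, 19, 24, 101, 23, 20, 9 and 31 up to the rule on medians, and to 37 and 41 with Cy5 or Cy3 alone. Regions in the dye component (542) went to 5210 at the SD of the animal. With loess, gains made up 53.4% of regions, and 63.4% without it. Windows (10) numbered 24 with no size rule, 3 at 0.4, 17 with Cy5 alone, 4 at 100 kb and 8 to 10 without each progeny in turn. Normexp lowered X medians to 0.55 in the dam and to 0.32, 0.46, 0.77, 0.81 and 0.57 in progeny 3 to 7. With Cy5 alone progeny 1 gave -0.068. Under the value table's names, the X medians were -0.96 in the sire, -0.95 in the dam and -0.95, -0.94, -0.96, -0.0096, 0.0065, -0.92 and -0.018 in progeny 1 to 7. The gain on chromosome 1 from 131173215 turned to -0.014 in the dam with normexp, under which 12 of the 31 named regions kept their call. Apart from the stated construction of each setting, the cause was not tested. Without dim probes, 12 of the 31 named regions kept their call and 2 lost it with the sign unchanged. Of the rest, 15 kept some probes but fewer than 3 and the others kept none, so these had no value. The robust SD of each animal limits short calls: at a score of 6 a 3-probe call needed a mean of 0.64 in progeny 3 and 0.26 in progeny 2. The GC correction, the gene fit and the gene lists were not run, as no mm9 genome or gene names were used, and the running median was not run on X, as it removes the shift itself. No paired analysis was possible because sire and dam were single animals with no number in common with several progeny.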

Other observations

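A gain on chromosome 14 from 26779391 to 27120884 was called in both parents and in progeny 3, where it covered 28 probes at a mean of 0.26. In the sire the call covered 5 probes at 0.36 and in the dam 8 probes at 0.35. On chromosome 13, a gain from 95703166 to 95712034 was called in the sire and in progeny 1, 2 and 5, at 0.32, 0.37, 0.35 and 0.34. It lay at 0.27 in progeny 3 and 0.24 in progeny 7, not called, and a single probe made up 88.3% of the summed size in a carrier. A loss on chromosome 14 from 61798066 to 61819370 was called in progeny 3, 5 and 6, at -0.50, -0.44 and -0.36. It was not called in the dam, progeny 4 and progeny 7, at -0.26, -0.33 and -0.29, and lay at -0.02, -0.03 and -0.02 in the sire, progeny 1 and progeny 2. The dam and progeny 3 to 7 thus lay apart from the sire and progeny 1 and 2, as at the chromosome 8 gain. These regions were chosen after their values were seen.

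The T cell receptor alpha and delta genes lie on mouse chromosome 14. Whether the interval holding the losses called in all 9 animals overlaps them was not analysed here.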
